A study of Salmonella enterica subsp. enterica serovar Typhimurium str. LT2 with 6 samples.

How the data were processed

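Total RNA was taken from naringenin-treated and DMSO-treated cultures of Salmonella Typhimurium LT2. Per the labels' protocols, an overnight culture was diluted 1000-fold in a medium labelled LG-glu with 0.5% glucose and grown at 37 °C with shaking. Naringenin was added to 100 µg/ml, and the control received 2.5 µl of DMSO. Per the same protocols, 10 µg of RNA from each side was reverse transcribed with random primers and aminoallyl-dUTP, and the cDNA was coupled to Cy3 or Cy5. The length of treatment is not given in the sources used here. The series' design text describes 3 control and 3 treated biological replicates in a dye-swapped layout, and 6 arrays are given.

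The deposited scanner values of each array are foreground and local background intensity in the red (Cy5) and green (Cy3) channels, given per the file headers as medians and on a linear scale. Each deposited file holds a single row for each of 5351 identifiers, with whole, half-step or quarter-step values. Repeated spots were therefore probably averaged by the authors, which was not tested. Foreground intensities ran from 62.5 to 64404. The files hold no spot flags, print blocks or control spots, and the scanner software is not given in the sources used here. The identifiers fall into 4 classes by prefix, with 4491 NTORF, 11 NTORFB, 810 ORF and 39 ORFB identifiers, and the meaning of the prefixes is not given in the sources used here. No column, label or gene table used here pairs them with gene names. The 28 gene lists fixed before the data were examined could therefore not be tested, and neither camera nor fry was run.

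A deposited table of the authors' processed values holds 5445 rows, 94 more than the scanner files, with its own row numbers and no identifiers. In the columns of replicates 2, 3, 5 and 6, its rows follow the order of that array's file, with the 94 extra rows after the first 4496 identifiers, and the sign is that of naringenin over DMSO. In these 4 columns the slope of the deposited values on the log2 ratio of the scanner values, over the brighter identifiers, was 0.691, 0.691, 0.644 and 0.685, with correlations of 0.99 to 0.999. The slope of a natural log is 0.693, so the authors' deposited values were read as natural log ratios and divided by that factor. The medians of these 4 columns, on the natural log scale, were −0.00561, 0.00277, 0.00526 and 0.0234. The background correction and the centring method behind them stay unknown. The columns of replicates 1 and 4 followed none of the 6 files (largest absolute correlation 0.0312 in the same row order, and 0.173 and 0.151 over a stretch of rows at any shift). They were not used, and their scale and direction are unknown; as deposited, their medians were 0.00116 and 0.0171.

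The scanner values were processed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50, which keeps every value positive and draws the ratios of dim identifiers towards 0. Each array was normalized by loess within the array, which sets the average ratio to 0 at each brightness, so a shift shared by most transcripts would not be seen. Each ratio was then turned to naringenin over DMSO from the dyes in the labels. No identifier was left out for low signal, and all had a value on all 6 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

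A Cy3 array and a Cy5 array of the same extracts are 1 replicate, so the test was made on 3 pair means (2 residual degrees of freedom, moderated by limma across identifiers). Since the labels do not name the pairs, limma was fitted under each of the 6 pairings. The mean ratio is the same in all of them, and the largest p and the largest SE of the 6 were kept for each identifier. Benjamini-Hochberg adjustment ran over all 5351 identifiers with a threshold of 0.05. If the true pairs are among the 6, this p is never smaller than that of the true pairing. The dye effect was tested with limma on the 6 arrays with a coefficient for dye orientation. The rule for named items, fixed before the data were examined, takes in each direction the 12 with the largest mean ratio among those past the threshold with the same sign on all 6 arrays. As no names are given, only the top 2 of each are printed. Runs of neighbouring numbers were defined by a gap of at most 3, after the data had been seen, and compared with 1000 shuffles of the changed identifiers over the NTORF numbers.

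The test on pair means was tried on simulated log ratios of 5351 identifiers, with dye coefficients and limma's moderated spread taken from the real arrays. The noise was drawn independently for each identifier and split equally between culture and array, which is an assumption. No intensities were simulated, so background correction, loess and the behaviour of dim identifiers were not tested. At 1.5-fold 94% of 67 changed identifiers were recovered, and at 2-fold and 4-fold 100%. Of 200 calls 4 were false, and with no change at all there were 0 calls. Alternatives covered the pairing, the use of all 6 arrays as replicates, background correction, normalization, filters on dim identifiers, the moderation of variances, the authors' table and leaving out each array or each possible pair.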

Results

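The data describe how transcript levels in Salmonella enterica serovar Typhimurium LT2, a laboratory strain of this enteric bacterium, differed between cells given naringenin and cells given DMSO alone. Naringenin is a flavanone of citrus fruit, and DMSO is the solvent in which such compounds are commonly dissolved. Cells were grown at 37 °C with 0.5% glucose to an optical density of about 1, with naringenin at 100 µg/ml or the same volume of DMSO. RNA from 3 treated and 3 control cultures was compared on 6 microarrays of 2 colours, each holding treated cDNA in one dye and control cDNA in the other. Naringenin-treated cDNA carried Cy3 on replicates 1, 3 and 5 and Cy5 on replicates 2, 4 and 6. The design text gives 3 biological replicates in a dye-swapped layout. The 6 arrays were therefore taken as 3 dye-swapped pairs, 1 for each biological replicate, although the labels name no pairs. This number of replicates limits the precision of every value below.

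Each array gave a foreground and a background intensity in both channels for 5351 array identifiers. The median net intensity, foreground minus background, was between 180.5 and 301.5 in the red channel on replicates 1 to 5 and between 153.5 and 307.5 in their green channel. Replicate 6 was dimmer, with medians of 43 and 43.5. Identifiers at or below background in at least one channel made up 1.18% to 11.8% of an array. The array files do not pair their identifiers with genes, so changes are given by identifier and no gene or genome position is named. At most 2 identifiers that rose and 2 that fell are printed for the same reason.

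The study's single comparison asks which transcripts differ between naringenin-treated and DMSO-treated cells. After naringenin, 98 identifiers fell and 31 rose, 129 in all or 2.41% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3). At least 2-fold changes were falls in 53 identifiers and rises in 15, and at least 4-fold changes were falls in 25 and a rise in 1. A run of neighbouring identifier numbers held 35 of the 98 falls, with 34 of the 53 of at least 2-fold and 21 of the 25 of at least 4-fold. The 63 identifiers that fell outside it had a median log2 ratio of −0.67, and 19 of them fell at least 2-fold. Among identifiers that fell the median log2 ratio was −1.09, with a range from −3.33 to −0.40. Among those that rose it was 0.96, with a range from 0.47 to 2.02. Of the 129 identifiers, 127 had the same sign on all 6 arrays, which selection by a small p favours.

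**Figure D1:**
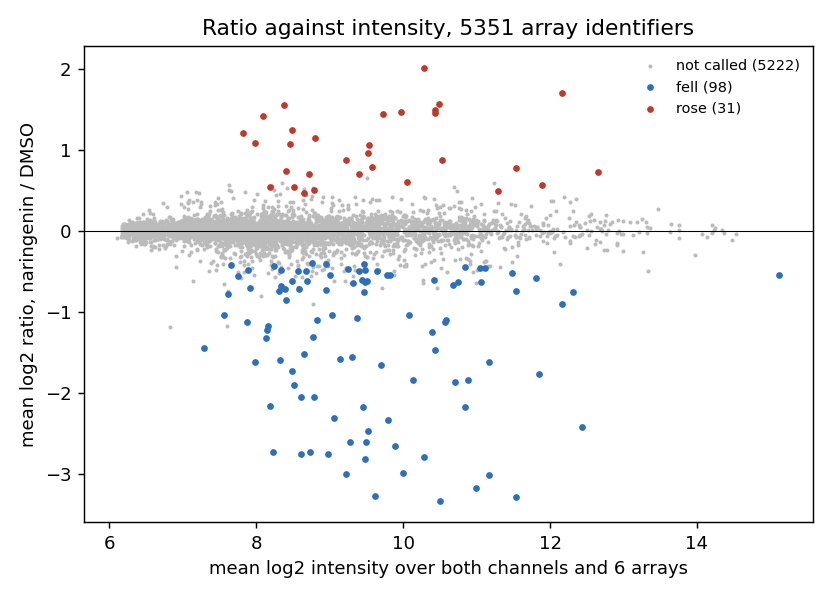
Mean log2 ratio of naringenin over DMSO (vertical axis) against mean log2 intensity over both channels and 6 arrays (horizontal axis), with a point for each of the 5351 identifiers. The 98 identifiers that fell (blue) reach a log2 ratio of −3.33 and the 31 that rose (red) reach 2.02, and grey points did not pass the test.

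Each SE below is limma's moderated SE, which draws on the spread of all identifiers, and is the largest over the 6 pairings. NTORF2869 had the lowest log2 ratio. The ratio was −3.33 ± 0.14 (SE, n = 3), a level 10.05-fold lower with naringenin, with a limma adjusted p of 0.000105. Its median net intensity over the 6 arrays was 436.5 with naringenin and 6395.75 with DMSO, and its log2 ratio on single arrays lay between −3.77 and −2.54. Net intensities are taken before the offset and loess, so their quotient differs from the fold given. The mean log2 ratio was −3.56 with an offset of 0, −3.62 with plain background subtraction and −3.06 with no background correction. The SE does not include this dependence on processing. On the dim replicate 6 its net intensity with naringenin was 55. The next identifier, NTORF2872, had a log2 ratio of −3.29 ± 0.08 (SE, n = 3; limma adjusted p = 1.36e-05). Its median net intensity was 1199.25 with naringenin and 12516.75 with DMSO, so it was well measured in both channels. The ratios of NTORF2869 and NTORF2872 differed by less than the SE of NTORF2869, and no order between them can be drawn.

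NTORF1527 had the highest log2 ratio, 2.02 ± 0.16 (SE, n = 3; limma adjusted p = 0.000905), or 4.04-fold. Its median net intensity was 3533.25 with naringenin and 716.25 with DMSO, and its ratio on single arrays lay between 1.37 and 2.44. NTORF0462 rose 3.26-fold, with a log2 ratio of 1.71 ± 0.08 (SE, n = 3; limma adjusted p = 0.000105). Its 6 arrays lay close together, from 1.48 to 1.86, around a median net intensity of 10554.75 with naringenin and 3182.375 with DMSO. None of the 4 identifiers passed limma's test of a difference between the dye orientations, with adjusted p from 0.212 for NTORF2872 to 0.788 for NTORF1527.

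**Figure D2:**
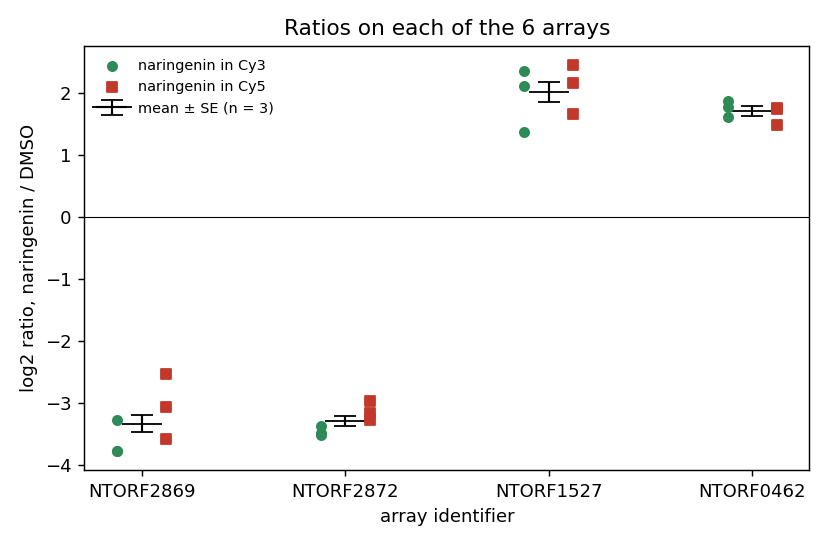
Log2 ratio of naringenin over DMSO (vertical axis) on each of the 6 arrays for 4 array identifiers (horizontal axis), with circles for naringenin in Cy3, squares for naringenin in Cy5 and black bars for the mean ± limma's moderated SE (n = 3). All arrays lie below −2.5 for NTORF2869 and NTORF2872 and above 1.3 for NTORF1527 and NTORF0462.

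Identifiers that fell often had neighbouring numbers. A run of such numbers, in which no gap between changed identifiers exceeded 3, spanned 38 identifiers, of which 35 fell, 0 rose and 3 did not pass the test. The median log2 ratio over the 38 was −2.18, and on single arrays this median lay between −2.63 and −1.68. The run held 11 of the 12 identifiers with the largest falls that had the same sign on all arrays, 34 of the 53 that fell at least 2-fold and 21 of the 25 that fell at least 4-fold. The other 63 identifiers that fell had a median log2 ratio of −0.67 and a lowest value of −2.75. In the NTORF class, which holds 4491 identifiers, 61 of the 96 that fell (63.5%) lay in runs of at least 2, against a median of 11 in 1000 shuffles of the numbers, and the largest run in any shuffle had 5. Of the 31 that rose, 15 lay in such runs, the largest of 4, against at most 8 and 3 in the shuffles. The files do not state whether the numbers follow the order of genes on the chromosome.

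**Figure D3:**
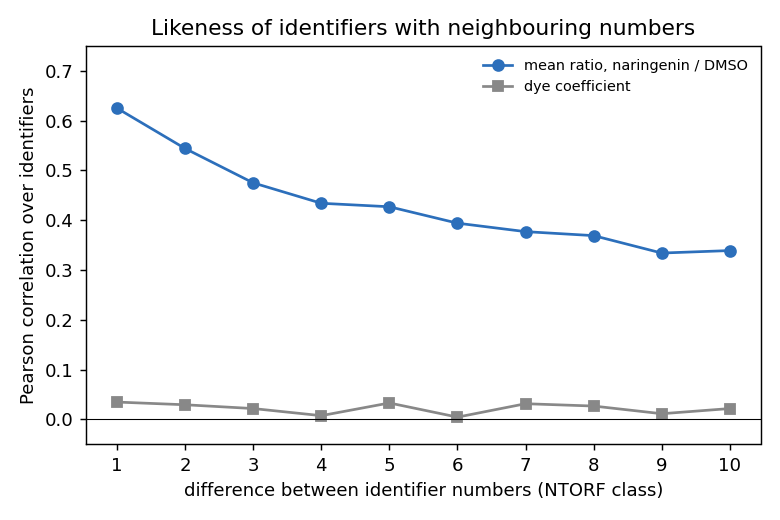
Pearson correlation over NTORF identifiers (vertical axis) between an identifier and the one whose number is higher by 1 to 10 (horizontal axis), for the mean log2 ratio of naringenin over DMSO (blue circles) and for the dye coefficient (grey squares). The ratio's correlation is 0.625 at a difference of 1 and 0.339 at 10, while the dye coefficient's is at most 0.0347.

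The dye effect was tested beside the treatment effect, since a swapped design separates them. In limma's fit to 6 arrays, 4 identifiers had a dye coefficient with an adjusted p under 0.05. An unadjusted p under 0.05 was found for 1113 of the 5351, a larger share than the 0.05 expected by chance, so dye differences may reach beyond the 4. The 4 became 0 under plain background subtraction and under median centring, 2 with scaling between arrays and 1 with a normexp offset of 0. None of the 4 was among the 129 identifiers changed by naringenin. All 129 had the same sign in the mean of the Cy3 arrays as in the mean of the Cy5 arrays. Over all identifiers, which are not independent replicates, the means of the 2 orientations had a Pearson correlation of 0.57 and a Spearman correlation of −0.16.

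The labels do not say which Cy3 array and which Cy5 array hold the same extracts, so every p is the largest over the 6 possible pairings. A single pairing gave between 136 and 472 identifiers, and pairing the arrays by neighbouring replicate numbers gave 305. Each of these lists holds the 129 by construction. The count was lower with trended and robust moderation (72, with 18 that rose and 54 that fell), with median centring (83, with 22 and 61) and in the 4 usable columns of the authors' table (53, with 11 and 42), and it was 0 without limma's moderation under the pairing by neighbouring numbers (610 at an unadjusted p under 0.05), which gave the 305 with moderation.

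**Figure D4:**
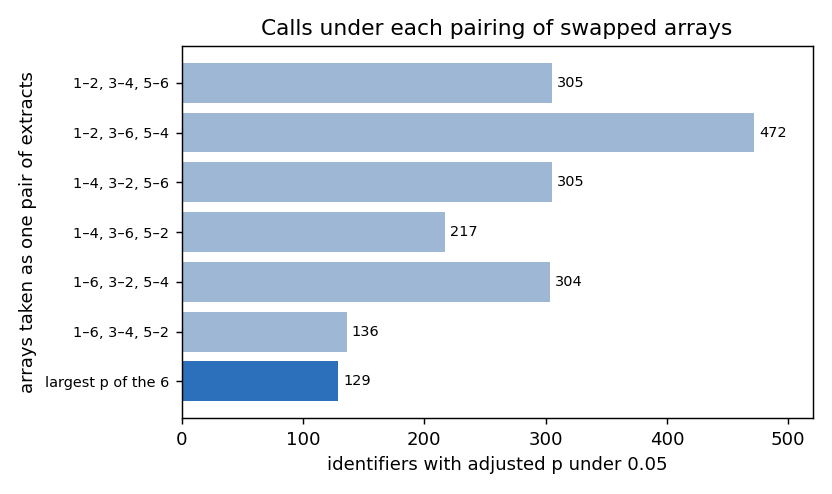
Number of identifiers with a limma adjusted p under 0.05 (horizontal axis) under each of the 6 ways to pair a Cy3 array with a Cy5 array (pale bars, named by replicate numbers) and when the largest p of the 6 is kept (dark bar). The pale bars run from 136 to 472 and the dark bar is 129.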

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

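The tests in this part were fixed before their results were seen, but the patterns they address were found in the same data. The processing with an offset of 0 and the scaling of arrays to a common brightness were chosen after seeing the data.

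Replicate 6 stood apart from the other arrays in 2 of 10 measures examined. The rule was Dixon's gap over range, which was 0.657 for the SD and 0.633 for the mean fall, against a bound of 0.625. Its median net intensities did not pass this rule (0.532 in red and 0.417 in green). Chance sets apart about 5% of single measures. The 10 measures come from the same arrays and are not independent, so 2 of 10 cannot be read as an excess. The SD of its log2 ratios over all identifiers was 0.2524, against 0.352 to 0.404 on replicates 1 to 5. The mean log2 ratio of the 98 identifiers that fell was −1.035 on replicate 6 and between −1.51 and −1.33 on the others. With a normexp offset of 0 in place of 50, the mean on replicate 6 was −1.50 and that on the others lay between −1.61 and −1.48. With all arrays first scaled to the same median net intensity, it was −1.33 against −1.46 to −1.34. With no background correction the mean on replicate 6 was −0.935 against −1.34 to −1.05, again the smallest mean fall. The SD of replicate 6 was 0.472 against 0.407 to 0.532 on the others with an offset of 0. With the arrays scaled first it was 0.348 against 0.344 to 0.403. In both settings it lay within the range of the others. With no background correction it was 0.236 against 0.271 to 0.317, the smallest SD. The rule that set replicate 6 apart was not applied under these other settings.

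For 4 identifiers the ratio differed between the dye orientations by limma's test of the dye coefficient (smallest adjusted p 0.00317, 3 arrays in each orientation). Their absolute coefficients lay between 0.59 and 0.769 on the log2 scale, all 4 had opposite signs in the 2 orientations, and 0 of them was changed by naringenin. The count was 0 under median centring and under plain background subtraction, and 1 to 3 with any single array left out.

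Over all identifiers, replicates 1 and 2, which carry opposite dyes, ranked the ratios in opposite order. Their Spearman correlation was −0.429 and their Pearson correlation was 0.127. Arrays of the same dye orientation had Spearman correlations of 0.142 to 0.478 with each other. The other pairs of opposite orientation had −0.145 to 0.276, so ranks were more alike within a dye orientation on all 6 arrays. A bias limited to dim identifiers is argued against by the brightest 25% of identifiers. There the Spearman correlation of replicates 1 and 2 was still −0.326 (95% interval −0.379 to −0.27). A wrong dye label on either array is argued against by the sign of the changes: of the identifiers called without the array, 90.9% kept their sign on replicate 1 and 92.9% on replicate 2. A dye bias of single identifiers at any brightness remains a candidate explanation, since the dye difference of replicates 1 and 2 followed that of the other 4 arrays with a Spearman correlation of 0.239 (95% interval 0.216 to 0.265). The size of that correlation leaves room for other sources particular to these 2 arrays, and no biological explanation was tested. Both intervals come from resampling identifiers on the same arrays. They measure spread over identifiers and not over arrays or cultures.

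More identifiers fell than rose, 98 against 31. The largest run of neighbouring numbers held 35 of these falls and 63 lay outside it. As neighbours had correlated ratios, the falls are not independent counts. The share that fell was 76% under loess and 73.5% under median centring. As both set the centre of each array near 0, this compares ways of centring and leaves centring itself open: the bound set beforehand for it was wrong, and a shift shared by most transcripts would not be seen. The dim replicate 6 is argued against, since 70.8% of calls fell in the fit to the other 5 arrays with a dye coefficient, and 69.3% in the same fit to all 6. A response to naringenin that lowers more transcripts than it raises may remain, as a hypothesis, and cannot be told apart from such a shift.

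The count of 129 was set against the other 31 sign patterns of the 6 arrays (32 patterns in all, the real one included). Only 1 of the 32, the real pattern, gave as many, and the highest of the others gave 0. Turning the sign of some arrays sets a real change against itself across arrays. Such identifiers could hardly be called under another pattern, so the 0 says little about chance. As the arrays stand for 3 replicates, which allow only 4 patterns, the share cannot come under 25%.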

How the results depend on the processing

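Alternatives were fixed before the data were examined, except the offset of 0, the arrays scaled to a common brightness and the restriction to NTORF identifiers, which were chosen after seeing the data. The 129 changed identifiers kept their direction in every alternative in which they were measured, and the cause of the moves below was not tested unless stated. Fitted under a single pairing, the test called 305 identifiers (100 rose, 205 fell) for neighbouring replicate numbers, and 472 (161 and 311), 305 (94 and 211), 217 (58 and 159), 304 (91 and 213) and 136 (32 and 104) for the other 5. These counts are higher by construction, since the largest p of the 6 was kept. Taking the 6 arrays as replicates gave 296 (91 rose, 205 fell) with a dye coefficient and 254 (78 and 176) without one. Median centring gave 83 (22 rose, 61 fell), all among the 129. Moderation with trend and robust gave 72 (18 and 54), all among the 129. The 4 matched columns of the authors' table gave 53 (11 and 42), of which 49 were among the 129, and a median log2 ratio of −2.53 over the run of neighbouring numbers. The scanner values of the same 4 arrays gave 168 (51 and 117), so the number of arrays does not account for the lower count. Without limma's moderation, with neighbouring numbers paired and at 2 residual degrees of freedom, 0 identifiers passed (0 rose, 0 fell, 0 at least 2-fold), although 610 had an unadjusted p under 0.05, against 305 that passed with moderation under the same pairing. The adjusted p of the 4 named identifiers was then between 0.162 and 0.244, against at most 0.0393 in all other settings. The count changed at least 2-fold was within 1.5 times of 68 in the remaining settings. No background correction, plain subtraction, scaling between arrays, leaving out the dimmest 25%, leaving out identifiers at or below background, an offset of 0, arrays scaled to a common brightness and NTORF identifiers alone gave 120, 131, 142, 166, 158, 123, 162 and 142 calls. The 4 identifiers with a dye effect became 0 under plain subtraction, 0 under median centring, 2 under scaling between arrays and 1 with an offset of 0.

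Leaving out single arrays, in the fit to all arrays with a dye coefficient, gave 276 calls without replicate 1, 238 without 2, 195 without 3, 201 without 4, 234 without 5 and 260 without 6, against 296 with all 6. Each of the 6 lists held all 129, but this fit takes arrays as replicates and calls more identifiers than the main test. Leaving out a Cy3 and a Cy5 array together gave 77 without replicates 5 and 2, 218 without 1 and 6, 199 without 3 and 2 and 196 without 3 and 6, and counts within 1.5 times of 129 for the other 5 pairs. Over all these leave-outs the count ran from 77 to 276, those that rose from 21 to 85, those that fell from 56 to 191, those changed at least 2-fold from 56 to 73, and those with a dye effect from 1 to 3. The named identifiers passed the threshold in all of them. Print-tip loess was not run because no print blocks are given, and the filter on spots marked by the scanner was run only for identifiers at or below background. A rule of at least 4 arrays would leave out nothing, since no value is missing. The gene lists, with camera at an estimated correlation and fry, were not run because no identifier is named. Few dim identifiers were called, and whether this comes from low signal, from the offset or from a lack of change was not tested: the dimmest 25% of identifiers held 0 that rose and 1 that fell, and the brightest 25% held 18 and 62, with median SEs of 0.0799 and 0.095.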

Other observations

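The test on identifiers that were not called was chosen after the likeness of neighbours had been seen. Over the NTORF class the mean log2 ratio had a lag-1 correlation of 0.625 (95% interval 0.273 to 0.78) between neighbours, against at most 0.0533 in 1000 shuffles, and of 0.33 with the largest run left out. A position on the slide is argued against, since the dye coefficient of the same spots had a lag-1 correlation of 0.0347 (95% interval −0.00142 to 0.0683). Among identifiers that did not pass the test, neighbours still correlated at 0.267 (95% interval 0.22 to 0.313; at most 0.0537 in the shuffles), and at 0.196 where both had an unadjusted p of 0.05 or more. This is consistent with neighbouring genes being transcribed together, as a hypothesis, but the files do not tell what order the numbers follow, so other sources tied to the numbering stay open.

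The classes of identifiers differed in how often they changed. In the NTORF class 127 of 4491 changed (2.83%), and in the ORF class 2 of 810 (0.247%), both of which fell. None of the 11 NTORFB or 39 ORFB identifiers changed. The NTORF class against the other 860 identifiers gave p = 7.11e-08 in a two-sided Fisher's exact test over identifiers, which are not independent replicates. The median net intensity was 206.5 in the NTORF class, 121 in the ORF class, 21.75 in the NTORFB class and 4.5 in the ORFB class.

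In the authors' deposited table, the columns of replicates 1 and 4 correlated with each other at 0.296 over rows and with no other column above 0.0226 in absolute value. The 94 rows without a scanner identifier had a median natural log ratio of 0.0342 over the 4 matched columns, and 12 of them had the same sign in all 4, where chance gives 12.5% of rows.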
